A study of Mus musculus with 8 samples.

How the data were processed

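RNA purified by UCP1-TRAP was measured by RNA sequencing in 3 libraries of inguinal WAT, 2 of perigonadal WAT and 3 of BAT, all from female mice after cold. Per the labels, ribosome-bound RNA was immunoprecipitated with a rabbit antibody against GFP from freshly dissected tissue. Groups and replicate numbers came from the tissue labels and sample titles. Reads were aligned to the mouse genome build mm9 with TopHat and quantified with Cufflinks, per the submitters' processing notes, which give no versions. Each deposited file held FPKM (fragments scaled by transcript length and library size) for 28702 transcripts of 22552 gene symbols, with confidence bounds and coverage, computed by the authors for 1 library each. The options of Cufflinks and any scaling between libraries are not given in the sources used here. No date or sequencing batch is labelled, and no library of unbound or whole-tissue RNA was used here. Coordinates are those of the files, in mm9, from the first to the last base of a gene's transcripts.

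The files hold no read counts. For genes with 1 transcript, the fragment number was recovered from the deposited FPKM and its upper confidence bound, and 83.9 to 92.8 percent of the low values per library came out whole within 0.05. The estimated fragments over all genes were 565762, 533391 and 260664 in inguinal replicates 1, 2 and 3, 1179090.0 and 628662 in perigonadal replicates 1 and 2, and 362866, 398717 and 389213 in BAT replicates 1, 2 and 3. Only 14.6 (inguinal replicate 3) to 46.5 (perigonadal replicate 1) percent of the FPKM denominator lay on the listed transcripts, so FPKM totals differ between libraries. Where all libraries of a group list a gene at 0, the fold is a lower bound against 3 fragments over that group, which covers counting error only. Actb and Gapdh were above 0 in all libraries. Cufflinks divides fragments between similar transcripts, so values of close paralogs are uncertain.

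FPKM was summed over the transcripts of a gene. Genes with an FPKM of at least 1 in at least 2 libraries and a longest transcript of at least 300 nt were kept, which left 8958. A marker absent from BAT passes this filter only through WAT libraries and can hardly be called lower in WAT. The test was limma with a trend of variance on expression, on log2(FPKM + 1), two-sided, with all 8 libraries in 1 model of 3 groups and Benjamini-Hochberg adjustment within each of 4 comparisons at 0.05. Fold changes are on that scale and understate changes of low genes. Ratios are of mean FPKM. Gene lists were tested with camera at a preset correlation of 0.01 in 22 of 32 lists with at least 5 tested members, adjusted over lists and comparisons, and again with the correlation estimated from the residuals. A gene or list passed, or was called, at an adjusted p under 0.05. "Adjusted over the list alone" means Benjamini-Hochberg over the tested members of that list. The analysis ran in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

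The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule named 17 genes always (Ucp1, Cidea, Dio2, Ppargc1a, Prdm16, Zic1, Lhx8, Tbx1, Tmem26, Myh11, Acta2, Tagln, Cnn1, Adipoq, Lep, Pdgfra and Pdgfrb). It further named, for each comparison of a pair of depots, the 8 higher and 8 lower called genes with the largest log2 fold change, and 5 and 5 for the mean of both WAT depots, among those whose groups did not overlap and whose higher group had a mean FPKM of at least 5, leaving out predicted, clone and small RNA names. Of each list described it named the 2 to 4 members with the highest mean FPKM over all libraries among those called in the direction of most called members. With fewer than 2 called, it named the 2 members with the highest mean FPKM. Results of some genes that the rule takes are not reported here. The lists were the thermogenic core, classical brown, beige-selective and white adipocyte markers, pan-adipocyte genes, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, de novo lipogenesis, glycolysis, creatine and calcium cycling, adrenergic signalling, secreted adipokines, MRTF and SRF cytoskeletal targets, immediate early and heat shock genes, proliferation, Hox genes, other developmental transcription factors, and markers of smooth muscle, pericytes, skeletal muscle, macrophages, lymphocytes, endothelium, fibroblasts and matrix, mammary luminal cells and milk, basal and myoepithelial keratins, mesothelium, ovary, uterus and oviduct, nerve and Schwann cells, red blood cells and epidermis.

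Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum FPKM of 5, short genes kept, median-ratio scaling, quantile normalization, removal of the 10 most abundant genes with equal totals, a fit of only the groups compared, the replicate number as a block, no variance trend, the most abundant transcript in place of the sum, and each library left out in turn. Median-ratio factors were 1.21, 1.14 and 0.545 for inguinal, 1.81 and 1.16 for perigonadal and 0.928, 0.906 and 0.886 for BAT libraries. Median-ratio scaling without inguinal replicate 3, without perigonadal replicate 1 and with the replicate block were added after seeing the data. On simulated data with 100 genes changed 4-fold and 100 changed 2-fold, limma recovered 84 and 10 percent for inguinal WAT against BAT, 79 and 12 percent for perigonadal WAT against BAT, 74 and 11 percent for inguinal against perigonadal WAT and 97 and 16 percent for the mean of both WAT depots. False calls were 6, 6, 1 and 2 in the same order, over 8777, 8828, 8813 and 8802 genes. The simulation used a dispersion (spread beyond counting error) of 0.06 for every gene, left the lowest genes unchanged and gave all libraries the same FPKM scale. Recovery and false calls in the real libraries may therefore be less favourable. The correlation and covariance that shared BAT libraries alone would give came from 50 simulations of unchanged groups.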

Results

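Translating RNA was purified from UCP1-positive cells of 3 adipose depots of female mice of the strain labelled C57B/6 UCP1-TRAP. UCP1-TRAP stands for translating ribosome affinity purification driven by the Ucp1 gene, in which ribosomes of the marked cells carry a GFP tag and are pulled down with their mRNA by an antibody against GFP. UCP1 is the mitochondrial uncoupling protein that makes heat in brown and beige adipocytes. The mice were bred at 30 °C, weaned at 3 weeks into room temperature, moved to 4 °C at 4 weeks and sampled 2 weeks later, at 6 weeks of age. The 8 libraries comprised 3 from inguinal white adipose tissue (inguinal WAT), 2 from perigonadal white adipose tissue (perigonadal WAT) and 3 from brown adipose tissue (BAT). UCP1-positive cells of white depots after cold are commonly called beige adipocytes, and the title of the series asks about a smooth muscle-like origin of these cells. Either white depot was compared with BAT, and the white depots with each other.

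The libraries were shallow and unequal. An estimated 260664 fragments in inguinal replicate 3 and 1179090.0 in perigonadal replicate 1 marked the extremes, and FPKM totals ran from 75925 to 206549 in the same libraries. Between 5859 and 9548 genes per library had an FPKM of at least 1. The median log2 difference over all 8958 tested genes was 0.03 for inguinal WAT against BAT, 0.52 for perigonadal WAT against BAT, -0.50 for inguinal against perigonadal WAT and 0.28 for the mean of both WAT depots against BAT. After median-ratio scaling these medians were 0.01, 0.03, -0.01 and 0.02, so scaled values stand beside the deposited ones wherever the shift could matter. The labels do not say that the libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical.

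RNA purified from inguinal WAT held more of many smooth muscle, mammary epithelial and lipogenic genes and of some white adipocyte genes than RNA purified from BAT. It held less of some other genes, while Ucp1 itself did not pass the test. Ucp1 (chr8:85814247–85822355) had 1104 ± 447 FPKM (SD, n = 3) in inguinal WAT and 1432 ± 132 FPKM (SD, n = 3) in BAT (log2 fold change -0.47, SE 0.26, adjusted p = 0.697). Acta2 (chr19:34315581–34329826), the smooth muscle alpha-actin gene, had 51.4 ± 34.0 FPKM (SD, n = 3) in inguinal WAT against 0.202 ± 0.345 FPKM (SD, n = 3) in BAT (log2 fold change 5.29, SE 0.42, adjusted p = 1.70e-16). Scd1 (chr19:44468940–44482199), a fatty acid desaturase, was 9.32-fold higher in inguinal WAT, and Cox8b (chr7:148084841–148086345), a cytochrome c oxidase subunit of heart and brown fat, was 2.51-fold higher in BAT. In all, 197 genes passed, 155 higher and 42 lower in inguinal WAT, by limma with Benjamini-Hochberg adjustment. Median-ratio scaling called 420 (272 higher, 148 lower), and the count was 109 without inguinal replicate 1, 336 without inguinal replicate 3 and 123 without BAT replicate 1.

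Smooth muscle markers were higher in inguinal WAT for 10 of 19 tested genes and lower for 0, or 13 adjusted over the list alone, with a median log2 fold change of 1.62 (camera adjusted p = 1.48e-29, adjusted p = 0.129 with an estimated correlation). Of these 19 genes, 6 had a mean of at least 1 FPKM in BAT, so the filter on low values left little room for lower calls. Tagln (chr9:45737711–45744141), an actin-binding protein of smooth muscle, had 12.5 ± 7.93 FPKM (SD, n = 3) in inguinal WAT and was listed at 0 in all BAT libraries, at least 39.6-fold higher against a floor of 3 fragments over the group. Myh11 (chr16:14194620–14291501), smooth muscle myosin heavy chain, had 5.42 ± 2.42 FPKM (SD, n = 3) against 0.0211 ± 0.0366 in BAT (log2 fold change 2.58, adjusted p = 7.89e-07). Cnn1 (chr9:21903697–21913665), calponin, had 4.71 ± 2.67 against 0.164 ± 0.142 (2.21, adjusted p = 3.33e-05). Csrp1 and Flna, which bind actin filaments, had log2 fold changes of 2.43 (adjusted p = 2.74e-05) and 2.38 (adjusted p = 2.35e-05).

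Genes of the mammary gland were higher together with the smooth muscle genes. Mammary luminal and milk markers were higher in inguinal WAT for 9 of 14 tested genes, or 12 adjusted over the list alone (camera adjusted p = 2.30e-34, adjusted p = 0.0661 with an estimated correlation). Keratins and other markers of basal and myoepithelial cells were higher for 5 of 9, or 9 adjusted over the list alone (camera adjusted p = 4.67e-18, adjusted p = 0.129 with an estimated correlation). Of these 14 and 9 genes, 3 and 0 had a mean of at least 1 FPKM in BAT, so the filter on low values left little room for lower calls. Expi (chr11:83522506–83524862), now named Wfdc18 and coding for a secreted protein of the whey acidic protein family, had 60.8 ± 4.87 FPKM (SD, n = 3) in inguinal WAT and 0 listed in every BAT and perigonadal library, which was at least 37.4-fold higher than in BAT (log2 fold change 5.95, SE 0.39, adjusted p = 1.42e-20). Ltf, lactoferrin, had 13.2 ± 6.29 FPKM (SD, n = 3) in inguinal WAT and was listed at 0 in BAT (at least 66.4-fold), and so were the epithelial genes Krt8 (at least 19.9-fold) and Fxyd3 (at least 11.1-fold). The basal keratins Krt5 and Krt14 had 5.99 ± 3.94 and 5.64 ± 2.06 FPKM (SD, n = 3) in inguinal WAT and 0 in BAT, at least 28.3-fold and 23.1-fold higher. Lcn2, lipocalin 2, a member of the secreted adipokine list and of neither mammary list, rose by 3.58 on the log2 scale (adjusted p = 3.99e-09). Csn3, kappa-casein, had 13.6 ± 1.503 FPKM (SD, n = 3) in inguinal WAT and 14.0 ± 7.51 FPKM (SD, n = 3) in BAT. Mammary myoepithelial cells are known to contain smooth muscle actin and myosin.

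**Figure D1:**
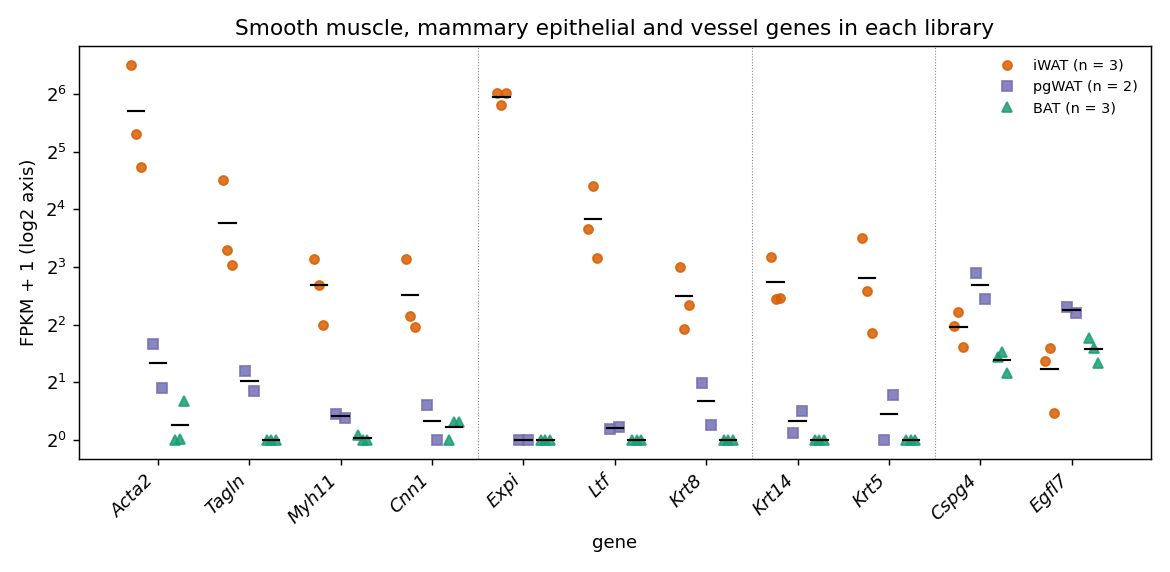
FPKM + 1 on a log2 axis for smooth muscle genes (Acta2, Tagln, Myh11, Cnn1), mammary luminal genes (Expi, Ltf, Krt8), basal keratins (Krt14, Krt5) and vessel genes (Cspg4, Egfl7), with 1 point per library and a bar at the mean of each depot. Acta2 averaged 51.4 FPKM in inguinal WAT, 1.51 in perigonadal WAT and 0.202 in BAT, while Cspg4 and Egfl7 had their highest means in perigonadal WAT.

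Fatty acid synthesis genes were higher in inguinal WAT than in BAT. Of 16 de novo lipogenesis genes, 10 were called higher and 0 lower, or 12 higher adjusted over the list alone, with a median log2 fold change of 1.77 (camera adjusted p = 9.88e-40, adjusted p = 0.109 with an estimated correlation). Scd1 had 841 ± 449 FPKM (SD, n = 3) against 90.2 ± 31.0 FPKM (SD, n = 3) (log2 fold change 3.14, SE 0.32, adjusted p = 7.50e-12). Fasn, fatty acid synthase, had 496 ± 183 against 57.2 ± 23.4 (adjusted p = 5.31e-11). Me1, malic enzyme, had 268 ± 65.7 against 40.4 ± 0.805 (adjusted p = 1.56e-08). White adipocyte markers were higher for 3 of 12, or 6 adjusted over the list alone (camera adjusted p = 3.70e-06, adjusted p = 0.452 with an estimated correlation). Retn (chr8:3655770–3659818), resistin, had 41.3 ± 9.96 FPKM (SD, n = 3) against 1.83 ± 2.64 FPKM (SD, n = 3) (log2 fold change 4.29, SE 0.44, adjusted p = 1.02e-11). Car3 (chr3:14863538–14872373), a carbonic anhydrase abundant in adipocytes, had 97.6 ± 12.6 FPKM (SD, n = 3) against 3.21 ± 2.01 FPKM (SD, n = 3) (log2 fold change 4.69, SE 0.42, adjusted p = 4.36e-14). Lep, leptin, had 1.81 ± 2.36 FPKM (SD, n = 3) and 0.0648 ± 0.112 FPKM (SD, n = 3), and its adjusted p was 0.238. Of 8 tested beige-selective markers, 1 was called, Slc27a1, a fatty acid transporter (log2 fold change 2.50, adjusted p = 2.05e-05), also 1 adjusted over the list alone and 2 without inguinal replicate 3. The camera test of the beige list gave adjusted p = 0.0201, adjusted p = 0.699 with an estimated correlation, and it missed the threshold without inguinal replicate 1 (adjusted p = 0.139) or 2 (adjusted p = 0.137). Tbx1 and Tmem26, the beige markers used most often, had 0.630 ± 0.554 and 0 FPKM in inguinal WAT and stayed below the minimum for testing.

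Pan-adipocyte genes had 1 of 23 called higher, also 1 adjusted over the list alone (camera adjusted p = 0.467, adjusted p = 0.992 with an estimated correlation), the complement gene Cfd, and 3 without inguinal replicate 3. Fabp4, the fatty acid-binding protein of adipocytes, had 3279 ± 1019.6 FPKM (SD, n = 3) against 2735 ± 279 FPKM (SD, n = 3) (log2 fold change 0.21, adjusted p = 0.973). Adipoq, adiponectin, had 202 ± 70.1 against 179 ± 30.6 (adjusted p = 0.995). Glycolysis had 1 of 18 genes called higher, also 1 adjusted over the list alone, with a median log2 fold change of 0.30 (camera adjusted p = 0.00353, adjusted p = 0.710 with an estimated correlation). The number called was 0 without inguinal replicate 1 or 2 or BAT replicate 2 or 3 and 6 without inguinal replicate 3.

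A few genes of the thermogenic program and of the respiratory chain were called lower in inguinal WAT than in BAT. Of 24 thermogenic core genes, 3 were called lower and 0 higher, or 4 lower adjusted over the list alone and 6 lower and 1 higher after scaling, with a median log2 fold change of -0.33 (camera adjusted p = 4.71e-05, adjusted p = 0.699 with an estimated correlation). The called genes included Cox8b with 659 ± 278 FPKM (SD, n = 3) against 1652 ± 289 FPKM (SD, n = 3) (log2 fold change -1.42, SE 0.28, adjusted p = 0.000298). Cox7a1, another cytochrome c oxidase subunit, was the next, with 418 ± 142 against 1009.7 ± 153 (adjusted p = 0.00188). Slc27a2, a fatty acid transporter, had 17.9 ± 6.49 against 50.4 ± 4.61 (adjusted p = 0.0198). Cidea (274 ± 112 and 329.7 ± 40.8 FPKM), Dio2 (19.3 ± 12.2 and 33.2 ± 5.64) and Ppargc1a (6.18 ± 2.58 and 8.39 ± 4.28) did not pass, with adjusted p of 0.956, 0.424 and 0.983. The call of Cox7a1 was lost without BAT replicate 2 (adjusted p = 0.0540), and that of Slc27a2 without inguinal replicate 1 (0.0615) or BAT replicate 1, 2 or 3 (0.103, 0.182 and 0.136). Of 73 oxidative phosphorylation genes, 2 were called lower, or 5 adjusted over the list alone and 10 after median-ratio scaling, with a median of -0.51 (camera adjusted p = 7.98e-16, adjusted p = 0.647 with an estimated correlation). One was Ndufs5, a complex I subunit, with 10.8 ± 9.91 FPKM (SD, n = 3) against 48.6 ± 23.2 FPKM (SD, n = 3) (adjusted p = 0.000132, 0.0700 after scaling). The other was Cox8a (adjusted p = 0.0400), whose call was lost without BAT replicate 1, 2 or 3 (0.189, 0.399 and 0.0773). The number of called genes of this list was 5 without inguinal replicate 3 and 1 without BAT replicate 1, 2 or 3.

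Limma called 0 of 17 genes of the tricarboxylic acid cycle and 0 of 23 of fatty acid oxidation, also 0 adjusted over each list alone, with 1 and 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.927 and 0.907). Hadhb, of mitochondrial beta-oxidation, had 773 ± 196 and 630.2 ± 72.8 FPKM (SD, n = 3) in inguinal WAT and BAT. It also called 0 of 8 classical brown markers, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.698). Zic1 and Lhx8, transcription factors used as brown markers, had 0.265 ± 0.160 and 0 FPKM in BAT, and Prdm16, a regulator of brown fat identity, 0.733 ± 0.237, all below the minimum for testing.

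Other genes lower in inguinal WAT were the metallothioneins Mt2 (log2 fold change -2.52, adjusted p = 8.18e-05) and Mt1 (-1.88, 0.000558), beside Ddit3 (-2.02, 0.00123) and Gdf15 (-1.97, 0.000742). Gpx3, a secreted glutathione peroxidase, fell from 265 ± 109.9 FPKM (SD, n = 3) in BAT to 67.5 ± 31.1 FPKM (SD, n = 3) (-1.97, 0.000128). Mrpl42, of the mitochondrial ribosome, fell from 86.9 ± 14.9 to 23.9 ± 7.88 (-1.86, 0.000984). Med21, a Mediator subunit, was lower too (-2.02, 0.00156). Without inguinal replicate 1 the calls of Ddit3 (adjusted p = 0.0905), Gdf15 (0.0661) and Med21 (0.0716) were lost, and that of Med21 also without inguinal replicate 3 (0.0782).

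Markers of other cell types were mostly low. Of 18 endothelial, 14 pericyte and 20 macrophage markers, 3, 3 and 8 reached the minimum for testing. No endothelial or pericyte marker was called between inguinal WAT and BAT, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 by limma. Egfl7, an endothelial gene, had 1.33 ± 0.844 FPKM (SD, n = 3) and 1.98 ± 0.435 FPKM (SD, n = 3), and Cspg4, a pericyte gene, 2.88 ± 0.804 and 1.60 ± 0.328. Among macrophage markers Cd14 was called higher, also 1 adjusted over the list alone, at 2.14 ± 1.38 FPKM (SD, n = 3) (adjusted p = 0.0234), a call lost without BAT replicate 1 (0.154) or 3 (0.133), and Cd14 was below the minimum for testing without inguinal replicate 1 or 2. The camera test of the macrophage list gave adjusted p = 0.698. Pdgfra and Pdgfrb, receptors of fibroblasts and mural cells, had 0.543 ± 0.113 and 0.376 ± 0.248 FPKM (SD, n = 3) in inguinal WAT and stayed below the minimum. Fibroblast and matrix genes had 2 of 17 called higher, Gsn and Fstl1, or 3 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 1.23e-06, adjusted p = 0.608 with an estimated correlation). Both calls were lost without inguinal replicate 1 (adjusted p = 0.171 and 0.222), inguinal replicate 2 (0.119 and 0.0895) or BAT replicate 2 (0.0878 and 0.162), and that of Fstl1 also without BAT replicate 1 (0.0573) or 3 (0.149). Of 9 tested Hox genes, which mark position along the body axis, Hoxa10 and Hoxc10 were higher in inguinal WAT (adjusted p = 0.00396 and 0.00246) and 1 was lower, also 2 and 1 adjusted over the list alone (camera adjusted p = 0.0973). The lower gene, Hoxa5, was named after its value was seen, at 0.181 FPKM against 1.91 (log2 fold change -1.29, adjusted p = 0.0453). That call was lost without inguinal replicate 1 (0.218) or 2 (0.106) or BAT replicate 1 (0.317) or 2 (0.0719) or 3 (0.273).

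RNA purified from perigonadal WAT held more of lipogenic and some white adipocyte genes than RNA purified from BAT, while few smooth muscle and mammary genes passed the test. Scd1 had 3420.1 ± 1425 FPKM (SD, n = 2) in perigonadal WAT against 90.2 ± 31.0 FPKM (SD, n = 3) in BAT, 37.9-fold higher (log2 fold change 5.23, SE 0.35, adjusted p = 1.41e-19, 4.56 after median-ratio scaling). Car3 had 327 ± 247 FPKM (SD, n = 2) against 3.21 ± 2.01 FPKM (SD, n = 3) (log2 fold change 6.19, SE 0.47, adjusted p = 2.49e-17). Ucp1 had 1438 ± 220.4 FPKM (SD, n = 2), close to its mean in BAT (log2 fold change 0.00, -0.67 after scaling, adjusted p = 0.0629 after scaling). Limma called 464 genes, 440 higher and 24 lower in perigonadal WAT, where median-ratio scaling called 546, 236 higher and 310 lower. The count was 105 without perigonadal replicate 1, 739 without perigonadal replicate 2, 1326 without inguinal replicate 3, which enters through the shared spread, and 258, 268 and 267 without BAT replicate 1, 2 and 3.

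All 16 tested de novo lipogenesis genes were called higher in perigonadal WAT, also 16 adjusted over the list alone and 15 after scaling, with a median log2 fold change of 2.87, or 2.23 after scaling (camera adjusted p = 5.73e-51, adjusted p = 0.0789 with an estimated correlation). Fasn was 18.1-fold higher (log2 fold change 4.24, SE 0.38, adjusted p = 3.07e-14), Acly, ATP citrate lyase, 21.5-fold (adjusted p = 1.12e-13), Me1 10.8-fold (adjusted p = 2.77e-10) and the desaturase Scd2 35.5-fold (adjusted p = 6.43e-13). White adipocyte markers were higher for 6 of 12, or 8 adjusted over the list alone (camera adjusted p = 9.81e-07, adjusted p = 0.452 with an estimated correlation), and for 3 without perigonadal replicate 1. After scaling 5 of the 12 white adipocyte markers were called higher and 1 lower. Those called higher as deposited included Retn with 141 ± 46.8 FPKM (SD, n = 2) against 1.83 ± 2.64 FPKM (SD, n = 3) (adjusted p = 7.27e-16). Slc7a10, an amino acid transporter, was another, with 14.7 ± 15.7 against 0.0994 ± 0.172 (adjusted p = 2.02e-07). Cyp2e1, a cytochrome P450, had 119 ± 98.2 FPKM (SD, n = 2) against 1.57 ± 0.644 FPKM (SD, n = 3) (adjusted p = 1.46e-13). Trf, transferrin, had 69.7 ± 40.3 against 1.29 ± 0.817 (adjusted p = 5.44e-13). Beige-selective markers had 1 of 8 called higher, Slc27a1 (log2 fold change 3.89, adjusted p = 3.00e-09), or 3 adjusted over the list alone and 2 without inguinal replicate 3 and 3 without perigonadal replicate 2 (camera adjusted p = 0.0490, adjusted p = 0.710 with an estimated correlation). The beige list missed the threshold without inguinal replicate 3 (adjusted p = 0.119), perigonadal replicate 1 (0.0973) or 2 (0.0547) and after scaling (0.0579). Lep had 3.76 ± 2.68 FPKM (SD, n = 2) (adjusted p = 0.00188, 0.0734 after scaling, 0.298 without perigonadal replicate 1).

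**Figure D2:**
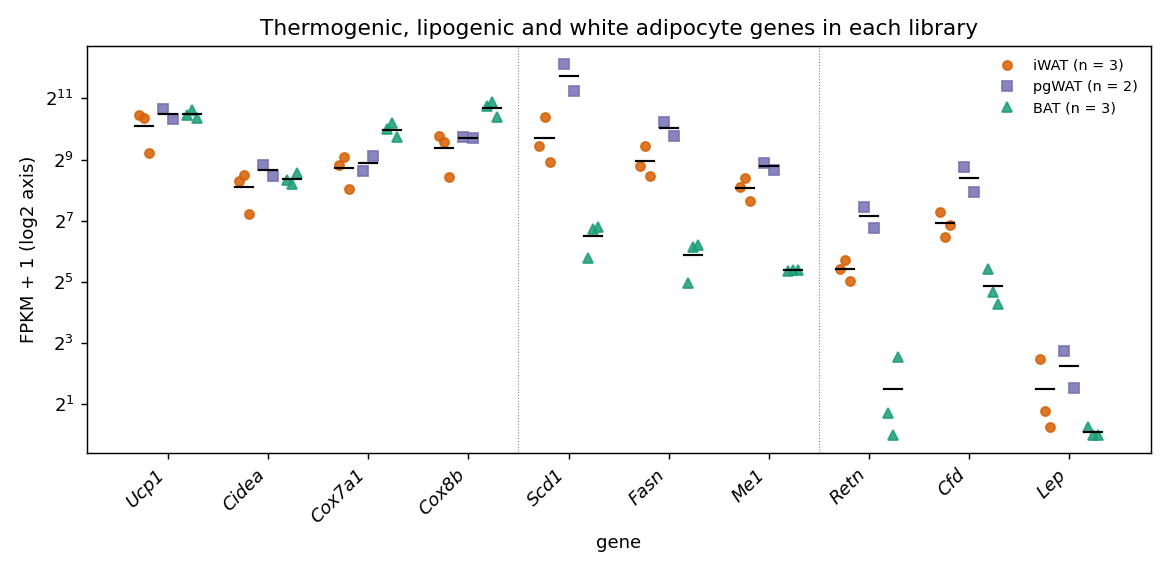
FPKM + 1 on a log2 axis for thermogenic genes (Ucp1, Cidea, Cox7a1, Cox8b), lipogenic genes (Scd1, Fasn, Me1) and white adipocyte genes (Retn, Cfd, Lep), with 1 point per library and a bar at the mean of each depot. Mean Ucp1 was 1104, 1438 and 1432 FPKM in inguinal WAT, perigonadal WAT and BAT, and mean Scd1 841, 3420.1 and 90.2.

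Of 23 pan-adipocyte genes, 6 were called higher, 11 adjusted over the list alone and 2 after scaling (camera adjusted p = 1.92e-05, adjusted p = 0.699 with an estimated correlation). Cfd was 12.04-fold higher (adjusted p = 1.22e-09, 0.00320 after scaling). Fabp4 had a log2 fold change of 0.90 (adjusted p = 0.0151) and of 0.23 after scaling (adjusted p = 0.585). Its call was also lost without perigonadal replicate 1 (0.821) or BAT replicate 2 (0.0556) or 3 (0.0779). The call of Pnpla2 was lost without inguinal replicate 1 (0.0533), perigonadal replicate 1 (0.731) or 2 (0.0647) or BAT replicate 1 (0.135) or 2 (0.124) or 3 (0.136), and that of Acsl1 without inguinal replicate 1 (0.0565), perigonadal replicate 1 (0.979) or BAT replicate 1 (0.190) or 2 (0.103) or 3 (0.142). The call of Adrb3, named after its values were seen, was lost without perigonadal replicate 1 (0.946). Called pan-adipocyte genes numbered 3 without inguinal replicate 1 or BAT replicate 1, 17 without inguinal replicate 3, 1 without perigonadal replicate 1 and 2 without BAT replicate 2 or 3. Glycolysis had 6 of 18 genes called higher, 8 adjusted over the list alone and 1 after scaling (camera adjusted p = 0.00623, adjusted p = 0.710 with an estimated correlation). Its test missed the threshold without perigonadal replicate 2 (adjusted p = 0.363) and after scaling (0.0595). Gapdh, a glycolytic enzyme, had 1418 ± 68.0 FPKM (SD, n = 2) against 610.3 ± 92.9 FPKM (SD, n = 3) (adjusted p = 0.00529, 0.272 after scaling, 0.112 without perigonadal replicate 1 and 0.0689 without BAT replicate 1). The call of Aldoa was lost without perigonadal replicate 1 (0.266) or BAT replicate 1 (0.0606). That of Ldha was lost without perigonadal replicate 1 (0.519) or 2 (0.0672) or BAT replicate 1 (0.115) or 2 (0.0930) or 3 (0.0854), and that of Pkm2 without perigonadal replicate 1 (0.353) or 2 (0.0776) or BAT replicate 1 (0.108) or 2 (0.0621) or 3 (0.0715). Called glycolysis genes numbered 11 without inguinal replicate 3, 0 without perigonadal replicate 1, 3 without perigonadal replicate 2 or BAT replicate 2 or 3 and 1 without BAT replicate 1. Classical brown markers had 1 of 8 called higher, or 3 adjusted over the list alone (camera adjusted p = 0.964), and 2 without inguinal replicate 2 or perigonadal replicate 2, 3 without inguinal replicate 3 and 0 without perigonadal replicate 1.

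Thermogenic core genes had 1 called higher and 1 lower of 24, or 2 and 3 adjusted over the list alone and 1 and 5 after scaling. Higher genes numbered 3 without inguinal replicate 3 and 0 without perigonadal replicate 1, and lower genes 2 without inguinal replicate 2, 3 without inguinal replicate 3 and 0 without perigonadal replicate 1 or BAT replicate 1, 2 or 3. Their median log2 fold change was 0.28, and -0.38 after scaling, and camera, which sets the list against all other genes, put it lower in perigonadal WAT (camera adjusted p = 0.0161, adjusted p = 0.842 with an estimated correlation). That test missed the threshold without perigonadal replicate 1 (adjusted p = 0.0859) or BAT replicate 2 (0.0514). Cox8b had 843 ± 10.8 FPKM (SD, n = 2) against 1652 ± 289 FPKM (SD, n = 3) (adjusted p = 0.0514, 0.00356 after scaling). Limma called 0 of 73 oxidative phosphorylation genes, 0 adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05, and 36 lower after scaling. The median of that list was -0.27, or -0.94 after scaling (camera adjusted p = 4.67e-18, adjusted p = 0.608 with an estimated correlation). Cox4i1, a cytochrome c oxidase subunit, had 785 ± 102 FPKM in perigonadal WAT and 945 ± 102 in BAT (adjusted p = 0.573, 0.0262 after scaling). The tricarboxylic acid cycle had 1 of 17 and fatty acid oxidation 1 of 23 genes called higher, or 2 and 1 adjusted over each list alone, and their medians of 0.39 and 0.43 turned to -0.28 and -0.24 after scaling (camera adjusted p = 0.973 and 0.794). Called genes of the cycle numbered 2 without inguinal replicate 1, 5 without inguinal replicate 3 and 0 without perigonadal replicate 1 or BAT replicate 1, 2 or 3. Those of fatty acid oxidation numbered 5 without inguinal replicate 3, 0 without perigonadal replicate 1 and 2 without BAT replicate 3.

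Smooth muscle markers had 2 of 19 called higher in perigonadal WAT than in BAT, or 3 adjusted over the list alone (camera adjusted p = 0.0584, adjusted p = 0.842 with an estimated correlation). After scaling the camera adjusted p was 0.00439. Cald1, caldesmon, was among the called markers (adjusted p = 0.000106). Acta2 had 1.51 ± 0.931 FPKM (SD, n = 2) (adjusted p = 0.180), and Myh11 0.333 ± 0.0521 (adjusted p = 0.558). The call of Cald1 was lost without perigonadal replicate 1 (0.0605), and the called smooth muscle markers numbered 0 without perigonadal replicate 1, 4 without perigonadal replicate 2 and 1 without BAT replicate 1 or 3. Mammary luminal markers had 1 of 14 called higher, Trf, and 1 lower, Csn3, also 1 and 1 adjusted over the list alone (camera adjusted p = 0.297). Of 9 basal markers, 1 was called, Oxtr, the oxytocin receptor, with 4.56 ± 1.33 FPKM (SD, n = 2) and 0 in BAT, also 1 adjusted over the list alone (camera adjusted p = 0.595). Fibroblast and matrix genes were higher for 12 of 17, 16 adjusted over the list alone and 7 after scaling (camera adjusted p = 2.73e-15, adjusted p = 0.412 with an estimated correlation). Their number was 1 without perigonadal replicate 1, where 3 of the 12 were below the minimum for testing. Of these, Dcn, decorin, had 28.9 FPKM in perigonadal replicate 1 and 4.79 in replicate 2, and without replicate 1 the calls of Gsn (adjusted p = 0.117) and Col3a1 (0.687) were lost. Endothelial and pericyte markers each had 1 of 3 called higher, or 2 and 2 adjusted over the list alone, namely Emcn (log2 fold change 1.40, adjusted p = 0.0223) and Mcam (1.91, 0.00226), both named after their values were seen. Emcn was below the minimum for testing without either perigonadal library. Its call was lost without BAT replicate 1 (0.0849) or 2 (0.0830) or 3 (0.0808), and that of Mcam without perigonadal replicate 1 (0.792). Limma called 0 of 8 macrophage markers, 0 adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.163).

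Hoxa10 (4.23 ± 1.31 FPKM (SD, n = 2) in perigonadal WAT, 0 in BAT) and Hoxc10 (2.21 ± 1.23, 0 in BAT) were the called Hox genes of perigonadal WAT (adjusted p = 5.11e-05 and 0.00844). They were 2 of 9, or 6 adjusted over the list alone (camera adjusted p = 0.00165, adjusted p = 0.531 with an estimated correlation). The call of Hoxc10 was lost without perigonadal replicate 1 (adjusted p = 0.504), and the called Hox genes numbered 1 without perigonadal replicate 1 and 5 without perigonadal replicate 2. Of the genes lower in perigonadal WAT, Csn3 had 0.937 ± 0.642 FPKM (SD, n = 2) against 14.0 ± 7.51 FPKM (SD, n = 3) (log2 fold change -2.87, SE 0.46, adjusted p = 6.38e-06). Mt2 had a log2 fold change of -2.50 (adjusted p = 0.000523), and Cntfr, the receptor of ciliary neurotrophic factor, of -1.90 (adjusted p = 0.00674). Ckb, Gdf15, Id2 and Tinagl1 were called as well, with log2 fold changes of -1.88, -1.78, -1.78 and -1.65. Rpl39l was listed at 0 in perigonadal WAT (adjusted p = 9.91e-05), a value that is uncertain because Rpl39l closely resembles Rpl39. Without perigonadal replicate 1 the calls of Ckb (0.353), Id2 (0.809) and Tinagl1 (0.146) were lost, and without perigonadal replicate 2 those of Mt2 (0.121), Cntfr (0.185), Gdf15 (0.159) and Tinagl1 (0.0627). Leaving out BAT replicate 1 ended the calls of Ckb (0.123), Gdf15 (0.0626), Id2 (0.0785) and Tinagl1 (0.0672), BAT replicate 2 that of Tinagl1 (0.0510), and BAT replicate 3 those of Gdf15 (0.0577) and Tinagl1 (0.0644).

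Between the white depots, RNA purified from inguinal WAT held more of some smooth muscle and mammary epithelial genes, and no thermogenic core gene passed the test. Acta2 had 51.4 ± 34.0 FPKM (SD, n = 3) in inguinal and 1.51 ± 0.931 FPKM (SD, n = 2) in perigonadal WAT (log2 fold change 4.24, SE 0.47, adjusted p = 3.57e-10, 4.68 and adjusted p = 0.000117 after median-ratio scaling). Expi was at least 33.8-fold higher in inguinal WAT, and Fxyd3 at least 10.02-fold. Ucp1 had a log2 fold change of -0.47 (adjusted p = 0.413) and of 0.20 after scaling (adjusted p = 0.874). Limma called 63 genes, 27 higher and 36 lower in inguinal WAT, and after scaling 28, 28 higher and 0 lower. The count was 11, 126 and 20 without inguinal replicate 1, 2 and 3, and 28 and 220 without perigonadal replicate 1 and 2.

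Smooth muscle markers were higher in inguinal than in perigonadal WAT for 4 of 19 genes, 5 after scaling, and for 9 with 1 lower adjusted over the list alone (camera adjusted p = 6.98e-30, adjusted p = 0.129 with an estimated correlation). The called genes were Acta2, Tagln (log2 fold change 2.59, adjusted p = 0.000116), Myh11 (2.19, 0.00117) and Cnn1 (2.12, 0.00264). Without inguinal replicate 1 Myh11 and Cnn1 missed the threshold (adjusted p = 0.05004 and 0.0854). Mammary luminal markers were higher for 7 of 14, or 10 with 1 lower adjusted over the list alone (camera adjusted p = 6.30e-60, adjusted p = 0.0345 with an estimated correlation). This was the only list of any comparison whose call held with an estimated correlation, and its called genes numbered 3 without inguinal replicate 1. Markers low in BAT and perigonadal WAT passed the filter on low values through inguinal libraries, so the filter set part of this direction. Basal markers were higher for 3 of 9, or 7 adjusted over the list alone (camera adjusted p = 5.13e-30, adjusted p = 0.0789 with an estimated correlation). Krt14 had 5.64 ± 2.06 FPKM (SD, n = 3) against 0.248 ± 0.237 FPKM (SD, n = 2) (adjusted p = 0.000203). Ltf had 13.2 ± 6.29 FPKM (SD, n = 3) against 0.154 ± 0.0266 FPKM (SD, n = 2) (adjusted p = 1.09e-08), and Csn3 a log2 fold change of 2.95 (adjusted p = 2.66e-05). Lcn2, of the secreted adipokine list, had a log2 fold change of 2.96 (adjusted p = 7.60e-05). The calls of Krt8 and Krt5 were lost without inguinal replicate 1 (adjusted p = 0.167 and 0.0795), that of Krt8 also without inguinal replicate 3 (0.115) or perigonadal replicate 2 (0.130), and that of Krt5 without perigonadal replicate 1 (0.0997). The call of Krt17, a basal keratin, was lost without inguinal replicate 1 (0.197) or 3 (0.0682) or perigonadal replicate 1 (0.115), and called basal markers numbered 1 without inguinal replicate 1 or perigonadal replicate 1. Il17b, a cytokine gene, was listed at 0 in perigonadal WAT and BAT and had 5.71 ± 3.92 FPKM (SD, n = 3) in inguinal WAT (adjusted p = 0.000116, 0.0657 after scaling, 0.0502 without inguinal replicate 3).

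The 6 tested vessel genes had lower values in inguinal than in perigonadal WAT, but limma called 0 of 3 endothelial and 0 of 3 pericyte markers. Adjusted over each list alone 3 and 1 were lower, also 3 and 1 at an unadjusted p under 0.05, and these lists had no list test. Egfl7 had 1.33 ± 0.844 FPKM (SD, n = 3) against 3.76 ± 0.242 FPKM (SD, n = 2), and Cspg4 2.88 ± 0.804 against 5.41 ± 1.38. Fibroblast and matrix genes were lower for 2 of 17, Dcn and Mfap5, or 8 adjusted over the list alone and 0 after scaling (camera adjusted p = 1.64e-06, adjusted p = 0.608 with an estimated correlation). The call of Mfap5 was lost without inguinal replicate 1, 2 or 3 (adjusted p = 0.0797, 0.0903 and 0.260) or BAT replicate 1, 2 or 3 (0.0563, 0.0572 and 0.0560). The number called was 0 without inguinal replicate 1 or 3 or perigonadal replicate 1, 7 without perigonadal replicate 2 and 1 without BAT replicate 1, 2 or 3, and without either perigonadal library 1 of the genes was below the minimum for testing. Without perigonadal replicate 1 the list leaned the other way (camera adjusted p = 0.881). Macrophage markers had 0 of 8 called by limma, with 1 higher and 2 lower adjusted over the list alone and also at an unadjusted p under 0.05 (camera adjusted p = 0.192). Hoxa5, named after its value was seen, was the called Hox gene of 9, also 1 adjusted over the list alone, at 0.181 FPKM in inguinal and 3.90 in perigonadal WAT (log2 fold change -2.06, adjusted p = 0.00314, 0.0588 after scaling). That call was lost without inguinal replicate 1 (0.0636) or perigonadal replicate 1 (0.0768). The camera test of the Hox list gave adjusted p = 0.0526, and 0.699 with an estimated correlation.

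De novo lipogenesis had 1 of 16 genes called lower in inguinal than in perigonadal WAT, Scd1, and 14 lower adjusted over the list alone, with a median of -1.09, or -0.42 after scaling (camera adjusted p = 1.31e-09, adjusted p = 0.452 with an estimated correlation). Scd1 had 841 ± 449 FPKM (SD, n = 3) against 3420.1 ± 1425 FPKM (SD, n = 2) (log2 fold change -2.09, SE 0.35, adjusted p = 0.000116, adjusted p = 0.201 after scaling). Its call was lost without inguinal replicate 3 (0.0502) or perigonadal replicate 1 (0.115), and the number called was 2 without inguinal replicate 2 and 0 without inguinal replicate 3 or perigonadal replicate 1. White adipocyte markers had 1 of 12 called lower, Slc7a10, or 4 adjusted over the list alone (camera adjusted p = 0.148), and 0 without inguinal replicate 1 or 3 or perigonadal replicate 1, 2 without inguinal replicate 2 and 3 without perigonadal replicate 2. Limma called 0 of 23 pan-adipocyte genes, with 3 lower adjusted over the list alone and 12 at an unadjusted p under 0.05 (camera adjusted p = 2.85e-06, adjusted p = 0.699 with an estimated correlation). It called 0 of 24 thermogenic core genes, 0 adjusted over the list alone and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.157). Of 73 oxidative phosphorylation genes limma called 0, with 1 lower adjusted over the list alone and at an unadjusted p under 0.05. The median of the oxidative phosphorylation genes was -0.30 as deposited and 0.35 after scaling (camera adjusted p = 0.125, adjusted p = 0.992 with an estimated correlation). The medians of the tricarboxylic acid cycle (-0.40, 0.27 after scaling) and of fatty acid oxidation (-0.45, 0.21 after scaling) changed sign likewise, with 0 genes of either called and 0 adjusted over each list alone, 0 and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.927 and 0.551). Of glycolysis 0 of 18, of the classical brown markers 0 of 8 and of the beige-selective markers 0 of 8 were called by limma, or 1 higher, 2 lower and 1 lower adjusted over each list alone, and 2, 2 and 2 at an unadjusted p under 0.05 in either direction (camera adjusted p = 0.880, 0.595 and 0.941).

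Other genes lower in inguinal than in perigonadal WAT were Snhg11, a noncoding RNA host gene (log2 fold change -2.28, adjusted p = 0.00354), Igf1, an insulin-like growth factor (-2.14, 0.00354), and Med21 (-2.23, 0.00676). Rbp4, the retinol-binding protein (-1.98, 0.0125) and Beta-s, a beta-globin gene (-1.88, 0.0299), were lower too, beside Dcn (-2.31, 0.00431) and Slc7a10 (-2.26, 0.00351). After scaling none of these 7 genes nor Scd1 was called (adjusted p = 0.370, 0.209, 0.361, 0.288, 0.400, 0.388, 0.226 and 0.201 in the order named). Without inguinal replicate 1 the adjusted p of Snhg11, Igf1, Med21, Rbp4, Beta-s, Dcn and Slc7a10 was 0.0854, 0.118, 0.157, 0.0994, 0.0854, 0.05004 and 0.0636. Without inguinal replicate 3 it was 0.360, 0.221, 0.260, 0.0959, 0.221, 0.462 and 0.326. Without perigonadal replicate 1 that of all but Snhg11 also missed the threshold, at 0.998, 0.0875, 0.742, 0.115, 0.998 and 0.998. Beta-s missed it without perigonadal replicate 2 too (0.126).

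**Figure D3:**
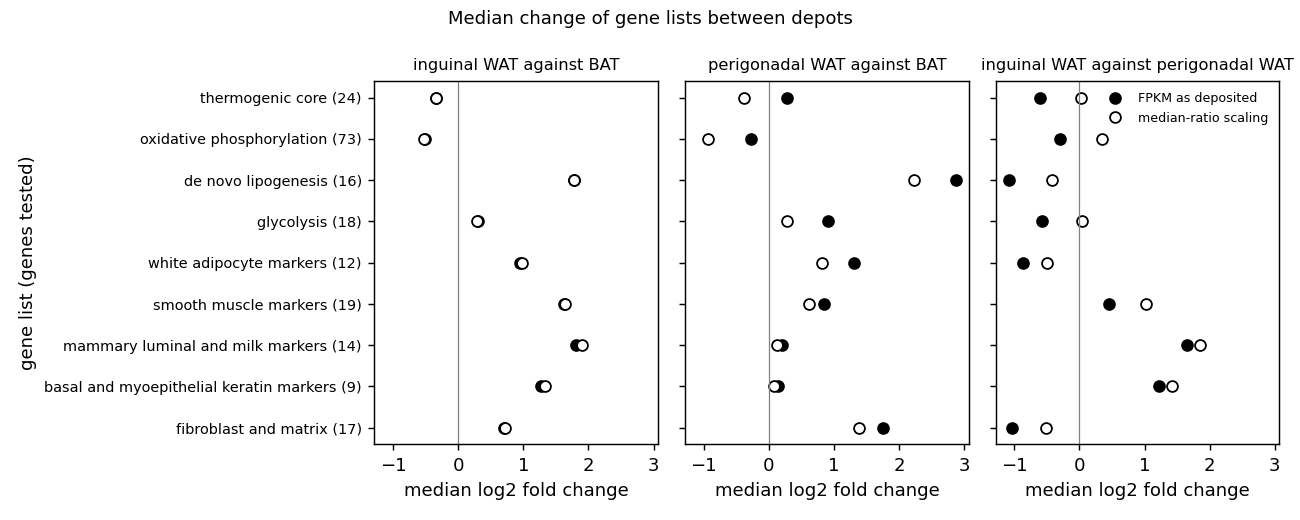
Median log2 fold change of 9 gene lists in the 3 comparisons between depots, from FPKM as deposited (filled circles) and after median-ratio scaling (open circles), with the number of genes tested in parentheses. Smooth muscle markers had medians of 1.62, 0.85 and 0.45, and de novo lipogenesis of 1.77, 2.87 and -1.09, from left to right.

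Taking the white depots with equal weight against BAT, most lipogenic genes were called higher in WAT, and Mt2 was lower. Part of the white adipocyte, smooth muscle, mammary luminal and matrix genes were called higher too. Tested by itself against BAT, inguinal WAT had 10 of 19 smooth muscle and 9 of 14 mammary luminal markers called higher. Perigonadal WAT had 2 and 1, with 1 luminal marker lower, so these calls were mostly those of inguinal WAT. Car3 had a log2 fold change of 5.44 (SE 0.38, adjusted p = 2.60e-19), Retn of 5.16 (adjusted p = 3.61e-17), Cyp2e1 of 4.41 (3.05e-14), Scd1 of 4.19 (2.11e-19) and Trf of 4.16 (4.37e-14). Mt2 (-2.51, adjusted p = 8.80e-06), Gdf15 (-1.88, 0.000229), Tinagl1 (-1.74, 0.000468), Id2 (-1.71, 0.00147) and Cntfr (-1.64, 0.00301) were lower. Ucp1 had a log2 fold change of -0.24 (adjusted p = 0.637), and of -0.57 after scaling, which passed (adjusted p = 0.0412). Limma called 367 genes, 319 higher and 48 lower in WAT, and 774 after median-ratio scaling, 373 higher and 401 lower. The count was 1268 without inguinal replicate 3, 210 and 603 without perigonadal replicate 1 and 2, and 197, 212 and 226 without BAT replicate 1, 2 and 3. Without perigonadal replicate 1 the call of Id2 was lost (adjusted p = 0.0514).

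De novo lipogenesis had 15 of 16 genes called higher in WAT, or 16 adjusted over the list alone (camera adjusted p = 3.90e-50, adjusted p = 0.0789 with an estimated correlation). White adipocyte markers had 5 of 12, or 8 (camera adjusted p = 3.85e-07, adjusted p = 0.452 with an estimated correlation). After scaling 5 of these 12 were called higher and 1 lower. Smooth muscle markers had 9 of 19 called higher, or 15 adjusted over the list alone (camera adjusted p = 1.10e-12, adjusted p = 0.449 with an estimated correlation). Beside them stood 7 of 14 mammary luminal markers (1 lower), 3 of 9 basal markers and 9 of 17 fibroblast and matrix genes, or 9, 4 and 15 adjusted over each list alone. Of the 9 basal markers, 5 were called higher in inguinal WAT tested by itself against BAT, and 1 in perigonadal WAT. Called luminal markers numbered 4 without perigonadal replicate 1, and the lower gene 0 without perigonadal replicate 1 or BAT replicate 2 or 3. Called matrix genes numbered 3 without perigonadal replicate 1 and 5 without BAT replicate 2. Oxidative phosphorylation had 2 of 73 genes called lower, 1 adjusted over the list alone and 37 after scaling (camera adjusted p = 4.86e-20, adjusted p = 0.608 with an estimated correlation). The thermogenic core had 3 lower and 1 higher of 24, also 3 and 1 adjusted over the list alone and 7 and 1 after scaling (camera adjusted p = 0.000482, adjusted p = 0.710 with an estimated correlation). The called oxidative phosphorylation genes were Ndufs5 (adjusted p = 0.0134), lost without BAT replicate 1 (0.0882), and Cox7c (0.0398), lost without perigonadal replicate 1 (0.189) or 2 (0.0616) or BAT replicate 1 (0.235) or 2 (0.298) or 3 (0.148). Called genes of that list numbered 4 without inguinal replicate 2, 16 without inguinal replicate 3, 1 without perigonadal replicate 1 or 2 or BAT replicate 2 or 3 and 0 without BAT replicate 1, and higher thermogenic genes 2 without inguinal replicate 3 and 0 without perigonadal replicate 1 or BAT replicate 1. Cox8b and Cox7a1 were lower with adjusted p of 0.000769 and 0.00112.

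Both white depots were compared with the same BAT libraries. Of the genes called higher than in BAT, 79 were called in inguinal and in perigonadal WAT, and of those called lower, 14. Independent lists of these sizes would share 7.61 and 0.113. After median-ratio scaling 132 higher and 110 lower genes were shared. No gene was called in opposite directions on either scale. Over all tested genes the log2 differences of the white depots from BAT had a correlation of 0.684 across genes, which are not independent replicates, against 0.446 in the simulation, and a covariance of 0.202 against 0.0773. The 3 BAT libraries could not be split into groups of at least 2, and part of the excess may come from these shared libraries.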

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

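The alternatives that join median-ratio scaling with a left-out library or with the replicate block were chosen only after the results were seen. The number of genes called for inguinal WAT against BAT, perigonadal WAT against BAT, inguinal against perigonadal WAT and the mean of both WAT depots against BAT was 197, 464, 63 and 367, and it stayed within 1.5 times of these without a variance trend. Numbers that moved further follow in that order of comparisons. A pseudocount of 0.1 gave 131, 214 and 5 for the comparisons of a pair of depots, and a pseudocount of 5 gave 146 for inguinal against perigonadal WAT. No filter on low values gave 11, 117, 9 and 39, and a minimum FPKM of 5 gave 124, 307 and 32 for the pairs of depots. The most abundant transcript alone gave 93, 174, 12 and 174. For inguinal WAT against BAT, inguinal against perigonadal WAT and the mean of both, median-ratio scaling gave 420, 28 and 774, quantile normalization 407, 39 and 674, and removal of the most abundant genes 440, 27 and 808. For inguinal against perigonadal WAT, short genes kept gave 40 and a fit of only these groups 35. Leaving out 1 library gave 109 to 336, 105 to 1326, 11 to 220 and 197 to 1268, and without either perigonadal library the lone sample is assumed to vary like the other groups. Median-ratio scaling without inguinal replicate 3 gave 19 for inguinal against perigonadal WAT and 800 for the mean of both, and without perigonadal replicate 1 332, 111 and 6 for the pairs of depots. The cause of these moves was not tested, apart from the fewer or more genes and libraries that a filter or a left-out library brings.

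The smooth muscle list passed with the preset correlation in inguinal WAT against BAT, inguinal against perigonadal WAT and the mean of both, under all alternatives run except the estimated correlation (adjusted p = 0.129, 0.129 and 0.449). With 1 library left out its adjusted p ran from 2.52e-35 to 9.02e-16, 2.94e-31 to 7.76e-20 and 4.38e-14 to 1.69e-07. In perigonadal WAT against BAT its adjusted p of 0.0584 became 0.000541 with a pseudocount of 0.1, 0.00439 after median-ratio scaling, 0.0349 without the most abundant genes and 0.0297 with only these groups. It was 0.0331 (without inguinal replicate 1) to 0.133 (without inguinal replicate 3) with 1 library left out, and after median-ratio scaling 0.00703 without inguinal replicate 3 and 0.0200 without perigonadal replicate 1, and the cause was not tested. The tricarboxylic acid list turned its direction under quantile normalization in inguinal WAT against BAT (adjusted p = 0.0130) and in the mean of both (0.0332), and between the white depots after median-ratio scaling (0.00351) and without the most abundant genes (0.0237). Fatty acid oxidation turned under quantile normalization in inguinal WAT against BAT (0.0263), after median-ratio scaling in perigonadal WAT against BAT (0.04998, and 0.0492 without inguinal replicate 3) and between the white depots (0.00837). Fibroblast and matrix genes turned between the white depots without perigonadal replicate 1 (0.881, the other end of the range with 1 library left out being 5.78e-13, and 0.761 after scaling), and Aldoa in the mean of both with the most abundant transcript (log2 fold change -0.23). The cause of these turns was not tested. Of 343 results of named genes, median-ratio scaling left 296 on their side of the threshold, ended 36 calls and added 11, no filter ended 132, and a pseudocount of 5 ended 4. Of 88 list results, the estimated correlation ended 44 calls and median-ratio scaling 4.

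The labels do not say whether libraries of the same replicate number share animals, and the numbers were not used as pairs. Correlations of deviations from the group means, across genes, were 0.126, 0.0804 and 0.1003 for inguinal WAT and BAT of the same number, -0.0272 and -0.0871 for inguinal and perigonadal WAT, and -0.0136 and -0.0184 for perigonadal WAT and BAT. Between inguinal WAT and BAT every library correlated best with its own number, which is a hint from the data and not from the design. The replicate block gave 280, 418, 88 and 468 calls, and with median-ratio scaling 420, 458, 10 and 750. With that block and scaling the smooth muscle list had an adjusted p of 0.00804 in perigonadal WAT against BAT, and the tricarboxylic acid list turned between the white depots (0.0458). In the simulation, which gave all libraries the same FPKM scale, 2-fold changes were recovered for 10 to 16 percent of simulated genes.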

Other observations

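The tests of explanations and the counts of other splits in this part were chosen only after the result was seen, while the gene lists were planned. Secreted adipokines had 4 of 17 genes called higher and 1 lower in inguinal WAT than in BAT, or 7 and 1 adjusted over the list alone (camera adjusted p = 1.92e-05, adjusted p = 0.452 with an estimated correlation), and the lower gene numbered 0 without inguinal replicate 1. In perigonadal WAT 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone and 4 and 1 after scaling (camera adjusted p = 4.16e-05, adjusted p = 0.456 with an estimated correlation). The higher genes numbered 3 without perigonadal replicate 1, and the lower gene 0 without perigonadal replicate 2 or BAT replicate 1 or 3. Besides Retn, Cfd and Lcn2, Cxcl14, a chemokine, was called higher in inguinal WAT (log2 fold change 1.64, adjusted p = 0.0196). That call was lost without inguinal replicate 1 (0.231) or 2 (0.118) or BAT replicate 1 (0.668) or 2 (0.0505). Rbp4 had 19.3 ± 9.60 FPKM (SD, n = 2) in perigonadal WAT against 1.62 ± 0.990 (SD, n = 3) in BAT (adjusted p = 2.26e-06).

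Developmental transcription factors other than Hox had 2 of 10 called higher in inguinal WAT than in BAT, Irx1 (adjusted p = 0.00784) and Irx2 (0.0254). Adjusted over the list alone 3 were higher and 1 lower (camera adjusted p = 0.0464, adjusted p = 0.726 with an estimated correlation, and 0.0693 after scaling). Irx1 and Irx2 were 0 FPKM in BAT and 2.04 and 1.59 in inguinal WAT. Irx1 was below the minimum for testing without inguinal replicate 1 or 2. The call of Irx2 was lost without inguinal replicate 1 (0.183) or BAT replicate 1, 2 or 3 (0.125, 0.119 and 0.110). The list missed the threshold without inguinal replicate 1, 2 or 3 (0.645, 0.652 and 0.0892), perigonadal replicate 1 or 2 (0.0549 and 0.0543) or BAT replicate 1 or 3 (0.0580 and 0.138). Between the white depots its test pointed to inguinal WAT (camera adjusted p = 0.00117, 0.656 with an estimated correlation and 0.122 after scaling) although its median was -0.38, or 0.11 after scaling. That call was lost without inguinal replicate 1 (0.719) or 2 (0.693).

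Cytoskeletal targets of MRTF and SRF, regulators of actin genes, had 1 of 15 called higher in inguinal WAT than in BAT, Actn1 (log2 fold change 1.39, adjusted p = 0.0226), or 5 adjusted over the list alone and 6 after scaling (camera adjusted p = 4.16e-05, adjusted p = 0.656 with an estimated correlation). The call of Actn1 was lost without inguinal replicate 1 (0.222) or BAT replicate 1 (0.103) or 2 (0.0993) or 3 (0.0910), and the number called was 0 without inguinal replicate 1 or BAT replicate 1, 2 or 3, 6 without inguinal replicate 3 and 2 without perigonadal replicate 2. The most abundant, Actb and Actg1, had 165 against 117 and 99.0 against 47.4 FPKM in BAT. Between the white depots limma called 0, with 0 at an unadjusted p under 0.05, and the list test pointed to inguinal WAT (camera adjusted p = 0.00336, adjusted p = 0.710 with an estimated correlation) although the median was -0.32, or 0.24 after scaling. It was lost without inguinal replicate 2 (0.0521) or perigonadal replicate 2 (0.0567). Limma called 0 of 16 adrenergic signalling genes in inguinal WAT against BAT, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.206). Gnas and Prkar2b, its most abundant genes, had 249.6 against 348 and 94.4 against 84.8 FPKM in BAT. In perigonadal WAT Adrb3, the beta-3 adrenergic receptor, was called higher (50.8 against 11.2 FPKM in BAT, adjusted p = 0.00965), a call lost without perigonadal replicate 1 (0.946), with 4 without inguinal replicate 3 and 0 without perigonadal replicate 1 called. Among 12 immediate early and heat shock genes Atf3, a stress transcription factor, was lower in inguinal WAT than in BAT (adjusted p = 0.0198), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.880). The call of Atf3 was lost without inguinal replicate 1 (0.108) or 3 (0.0763) or BAT replicate 1 (0.0964) or 3 (0.440). Dusp1 and Nr4a1 of that list had 7.69 against 6.42 and 6.67 against 7.94 FPKM in BAT. Of 5 creatine and calcium cycling genes Ckb was lower in inguinal WAT (5.33 against 14.4 FPKM in BAT, adjusted p = 0.0316), with 1 higher and 1 lower adjusted over the list alone. Its median was 0.30 while the test leaned lower (camera adjusted p = 0.964), and Atp2a2 had 25.02 against 27.4 FPKM in BAT. The call of Ckb was lost without inguinal replicate 2 (0.137) or 3 (0.314) or BAT replicate 1 (0.369) or 3 (0.0747).

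The remaining lists had fewer than 5 tested genes and no list test. For inguinal WAT against BAT, Mb, myoglobin, was the 1 lower of 3 skeletal muscle markers (0 against 3.88 FPKM in BAT, adjusted p = 0.000742, 0.0528 without inguinal replicate 3, and below the minimum for testing without BAT replicate 1 or 3), also 1 adjusted over the list alone, and Myl1 had 14.7 against 13.7. Igfbp5 was the 1 mesothelial marker tested and was higher (15.7 against 2.16 FPKM in BAT, adjusted p = 0.000209), also 1 adjusted over the list alone, while Igfbp6 had 0.207 against 0. Hoxa10 was the 1 higher of 2 ovary, uterus and oviduct markers, also 1 adjusted over the list alone, and Esr1 had 1.10 against 1.09 FPKM in BAT. Krt15 was the 1 higher of 3 epidermal markers (1.51 against 0 FPKM in BAT, adjusted p = 0.0284), also 1 adjusted over the list alone, and its call was lost without inguinal replicate 1 (0.0960) or 3 (0.0639) or BAT replicate 1 (0.144) or 2 (0.137) or 3 (0.125). Sbsn and Krt79 had 0.804 against 0.851 and 0.684 against 0.751. Limma called 0 of 4 nerve and Schwann, 0 of 3 red blood cell, 0 of 1 lymphocyte and 0 of 2 proliferation genes. Nerve genes had 1 higher and 1 lower at an unadjusted p under 0.05 and also adjusted over the list alone, with S100b at 10.7 against 23.4 and Pmp22 at 12.1 against 7.79 FPKM in BAT. Red blood cell genes had 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Hba-a1 at 0.687 against 1.27 and Hba-a2 at 0.0441 against 2.31. Lymphocyte markers had 1 higher in either way, with Coro1a at 1.05 against 0.201 and Cd3e at 0.611 against 0.158, and proliferation genes 0, with Pcna at 3.45 against 2.61 and Tyms at 0.419 against 0.560. Between the white depots Hba-a1, a globin gene, was lower in inguinal WAT (0.687 against 4.85 FPKM in perigonadal WAT, adjusted p = 0.0165). That call was lost without inguinal replicate 1, 2 or 3 (0.0854, 0.109 and 0.0502) or perigonadal replicate 2 (0.120). Actn1, Adrb3, Atf3 and Krt15 fall outside the naming rule and were chosen after their values were seen.

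Of 19 smooth muscle markers, 4 were called higher in inguinal than in perigonadal WAT, and the list call was lost with an estimated correlation (adjusted p = 0.129). RNA of whole blood vessels could not be decided on. The 6 tested endothelial and pericyte markers had a median log2 difference of -1.08 (-0.74 after scaling) with 0 above 0. They were only 3 of 18 and 3 of 14 listed genes, and Emcn passed the filter on low values only through the perigonadal libraries. The FPKM scale was argued against, because 5 smooth muscle markers were called higher in inguinal WAT after median-ratio scaling. Before scaling, the median log2 difference over all tested genes lay in the other direction (-0.50). RNA of mammary epithelial cells, which line the ducts of the inguinal fat pad in females, stays a candidate source. The 23 tested luminal and basal markers had a median log2 difference of 1.30 (quartiles 0.88 and 2.00) with 20 above 0. Markers low in BAT and perigonadal WAT passed the filter on low values through inguinal libraries, so the filter set part of this direction. Of the 14 luminal and 9 basal genes, BAT had 3 and 0 at a mean of at least 1 FPKM. The most abundant of them in inguinal WAT were Expi (60.8 FPKM), Trf (23.9) and Csn3 (13.6). Not all of these were particular to inguinal WAT. Trf had a higher mean in perigonadal WAT, and Csn3 had a similar mean in BAT. The purification against GFP is meant to remove mammary epithelial cells. A difference between the UCP1-positive cells of the depots stays open and was not tested.

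Of 16 de novo lipogenesis genes, 15 were called higher in the mean of both WAT depots than in BAT, and the list call was lost with an estimated correlation (adjusted p = 0.0789). The FPKM scale as the whole cause was argued against, because after median-ratio scaling the lower quartile of the log2 difference over 16 genes was 1.05 and 16 were above 0. RNA of white adipocytes without UCP1 may contribute, but the marker values cannot decide it. The 12 tested white adipocyte markers had a median log2 difference of 0.76 after scaling, with a lower quartile of 0.15 and 9 above 0. Markers below 1 FPKM in the BAT libraries pass the filter on low values only through WAT libraries, so the filter set part of this direction. Of these 12 genes BAT had 5 at a mean of at least 1 FPKM and other lists held 3, the most abundant in perigonadal WAT were Retn (141 FPKM) and Nnmt (58.7, 82.1 in BAT), and the purification against GFP is meant to remove such cells. A difference between UCP1-positive cells of the depots stays open and was not tested.

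Nearly all calls of perigonadal WAT against BAT were higher in perigonadal WAT. Without the deepest library, perigonadal replicate 1, the median log2 difference over all tested genes was 0.26, against 0.52 with it. That fit leaves 1 perigonadal library, so it cannot decide how much of the pattern comes from the deepest library. After median-ratio scaling 43.2 percent were higher, but that scaling removes any difference shared by most genes, whether of the libraries or of the depots (median from 0.52 to 0.03). The FPKM scale of the libraries and a broad difference between the depots therefore cannot be told apart, and both stay open.

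Of 10 splits of the 6 inguinal and BAT libraries, 1, the real one, called as many genes (197, highest other 3), and 10 splits are too few to reach a share of 0.05. For the mean of both WAT depots against BAT, 100 splits of all 8 libraries into groups of the same sizes were counted. Only 1, the real one, called as many genes (367). Among these splits 2 kept the real BAT group. Splits that mix depots add depot differences to the spread within groups, so lower counts are likely there. The highest other count, 247, came from a split that grouped inguinal replicate 2 with both perigonadal libraries. The labels do not say that the libraries come from separate animals, so these counts cannot exclude chance between animals.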
